A study of Danio rerio with 18 samples.

How the data were processed

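Transcript levels were measured on 18 Affymetrix arrays of regenerating caudal fin from adult male zebrafish (AB strain). Per the labels' protocols, fins were amputated at the branching point of the fin rays, and fish were injected on the day of amputation with liposome vehicle or with liposomes carrying TCDD (2,3,7,8-tetrachlorodibenzo-p-dioxin, a ligand of the aryl hydrocarbon receptor, AHR) to 50 ng/g. Regenerating tissue was taken at 1, 3 or 5 days post amputation (dpa). Each array holds RNA pooled from 10 fish, and each of the 6 groups has 3 arrays, so that every error given describes the spread between pools of 10 fish and not between fish. Replicates carry the letters A to E from the labels. Group and letter of each array came from the labels. The number of arrays limits the precision.

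The deposited values are intensity values on a linear scale, 1 per probe set, made by the authors with GCRMA per the submitters' processing notes. Its version and settings are not given in the sources used here. Scanner files were not used here, so that background correction, normalization and probe summary stand as the authors left them. The median intensity per array ran from 75.13 to 84.12. Of 15617 probe sets, 115 Affymetrix controls were left out of every test, leaving 15502. Gene names came from the platform annotation, updated by Entrez ID through a RefSeq gene table. 10795 probe sets had 1 symbol, 10711 of them found in that table, 135 had several symbols and 4572 had none. No gene was named from a probe set with several symbols. The symbols covered 8793 genes, each represented by its probe set with the highest mean over all arrays.

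Values were analysed as log2(intensity + 1), so that differences of dim transcripts are understated. limma 3.58.1 in R 4.3.3 fitted the 6 group means over all 18 arrays (lmFit, contrasts.fit, eBayes with a trend on the mean level). p-values were adjusted by the method of Benjamini and Hochberg over the 15502 probe sets of each contrast, and a probe set passed at an adjusted p under 0.05. Every adjusted p given for a gene comes from limma. The contrasts were TCDD against vehicle at each day, the mean of these 3 effects, the steps from 1 to 3 and from 3 to 5 dpa in each exposure, and an F test with 2 degrees of freedom for a TCDD effect that differs between days. All tests were two-sided. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

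A set of 24 gene lists was fixed before the data were examined: AHR targets, AHR complex, antioxidant response, matrix structural, matrix processing, bone and cartilage, blastema and patterning, cell cycle, retinoid, epidermis, myeloid cells, inflammation, lymphocytes, erythrocytes, skeletal muscle, vascular endothelium, pigment cells, nerve and glia, sterol synthesis, unfolded protein and heat shock, glycolysis, oxidative phosphorylation, liver and plasma, and ribosomal proteins. Lists were tested with limma's camera at its preset correlation between genes of 0.01, and again with a correlation estimated per list. Adjustment ran over all lists and the 3 within-day effects together. The mean effect, the vehicle course and the TCDD step from 1 to 3 dpa were adjusted as families of their own. Matches through old symbols that led to another gene (mtnr1ba, ephb2b) and a kinase let in by the ribosomal name pattern (rps6kal) were removed by hand before any fit. The symbol cd3eap in the lymphocyte list and hbegfb in the erythrocyte list were kept as fixed, although neither is a marker of those cells.

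Genes were named by a rule fixed before the data were examined: for each TCDD effect the 10 largest rises and 10 largest falls with a log2 difference of 1 or more, no overlap between the groups and a mean log2 level of 5 or more in the higher group. The rule added every measured AHR target and up to 4 members of each other list with the smallest adjusted p. For the vehicle course and the difference between days it took the 5 largest in each direction. Clone and locus names were counted, not named. List members named for the mean effect, and the probe sets named for the TCDD course, were chosen after their values were seen.

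The letters were checked for pairing through each array's deviations from its group mean, over probe sets with a mean level above the median. All 7 pairs of same-day arrays with the same letter correlated above 0.1 (0.20 to 0.70, median 0.57), against 2 of 20 same-day pairs with different letters (median -0.17). Across days, 23 of 24 same-letter pairs were above 0.1. The letters therefore pair the arrays, but the main fit, set beforehand, holds no letter term. Values given without mention of another fit come from it and ignore this pairing. Fits with the letter as a block are given beside them for counts, and for named genes and lists whose call they change. The labels do not say what a letter stands for.

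The fits were tested on simulated data before use, with 200 probe sets changed, all with a mean log2 level of 5 or more. In the comparison at 3 dpa over 15502 probe sets, simulated without a letter effect, 108 were called, 5 of them falsely. Of those changed by a log2 difference of 0.5, 1 and 2, 10.4%, 55.2% and 89.4% were recovered. With a simulated letter effect the main fit called 110, 1 falsely, and recovered 61.2% at a log2 difference of 1. The fit with the letter as a block called 139, 5 falsely, and recovered 77.6%. At 1 and 5 dpa, where the letters are unequal, this fit called 130 and 123, 9 and 3 falsely. It recovered 74.6% and 67.2% there. The simulated letter effects were drawn independently for each probe set. The list test at 3 dpa, over 8793 genes, called a shifted list in 100 of 100 simulations and an unshifted one in 5. These simulated genes were independent, which favours the preset correlation.

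Alternatives planned beforehand were a block for the letter over all days or within days, another pseudocount of 16, a repeated quantile normalization, median centring, a filter on dim probe sets (at or above the 40th percentile on 3 arrays or more), a constant prior variance, array weights, a minimum 2-fold change, 1 probe set per gene, fits of only the groups compared, and each array left out in turn. Added after seeing the data were the letter within days as a random block, the 3' minus 5' difference of the GAPDH control probe sets as a covariate, and fits without letters A and B, without letter C at 3 dpa, or with only the letters held by both exposures at a day. Lists whose call the block changed were tested with the block and an estimated correlation. The overlap of the steps from 1 to 3 dpa was also taken without letter C at 3 dpa and letter D at 1 dpa.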

Results

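Transcript levels were compared between TCDD and vehicle fish at 1, 3 and 5 dpa, with 3 arrays of pooled regenerating fin in each of 6 groups. The design asks how exposure to this AHR ligand alters the transcripts of a regenerating fin and how these change over the course of regeneration. The 3' minus 5' log2 difference of the GAPDH control probe sets, a sign of RNA quality, had group means of 1.86 to 2.62. It ran from 2.05 to 3.03 over the 6 arrays of letter B, and from 1.38 to 4.06 over the 3 arrays of letter C. The same difference of the actin control probe sets ran from 1.455 to 2.322 over all arrays.

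At 1 dpa, AHR-responsive cytochrome P450 genes stood among the largest rises with TCDD. cyp1c1 rose from 6.04 ± 1.33 to 11.72 ± 0.07 (log2 intensity, mean ± SD, n = 3), 51.4-fold, and cyp1a rose by 6.80 ± 1.16 (log2 difference ± SE, adjusted p = 0.018). fzd7a, a Wnt receptor, rose by 2.42 ± 0.33 (adjusted p = 0.0053) and zdhhc2, a palmitoyltransferase, by 1.78 ± 0.25 (adjusted p = 0.0066). rspo1, a secreted enhancer of Wnt signalling, rose by 3.18 ± 0.49 (adjusted p = 0.0098), and the collagenase gene mmp13a rose by 2.48 ± 0.46 (adjusted p = 0.038). Among the falls, asporin (aspn), a small proteoglycan of the matrix, fell by 1.72 ± 0.22 (adjusted p = 0.0041). The skeletal transcription factor sox9b fell by 3.23 ± 0.55 (adjusted p = 0.018).

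In all, 38 probe sets passed at 1 dpa, 25 higher and 13 lower. The genes mpx, fzd7a, zdhhc2, aspn and cyp2k6 passed with each array left out in turn, though cyp2k6 is dim (2.56 in vehicle and 2.92 in TCDD fish), under the 40th percentile. The probe set named mpx, a neutrophil peroxidase, rose by 3.70 ± 0.37 (adjusted p = 0.00034). Another set of that symbol had a log2 difference of -0.78 (adjusted p = 0.84). Their means over all arrays are 5.62 and 5.22, but the first includes the rise with TCDD. In vehicle fish the named set is the dimmer. Without vehicle replicate D the calls for cyp1a, cyp1c1, rspo1, cyb5a, nt5c2l1, sult6b1 and sox9b were lost, with adjusted p up to 0.142 over the arrays that ended them. Most of these calls were also lost without vehicle replicate E or TCDD replicate A, and that of cyp1a without TCDD replicate B. The call for mmp13a was lost without any 1 of 16 arrays (adjusted p up to 0.234). On vehicle replicates D and E the levels of cyp1a (4.48 and 4.19) and rspo1 (4.09 and 4.40) lie under the 40th percentile of the arrays, as does that of cyp1c1 on E (5.16). So do those of cyp1a, cyp1c1 and rspo1 on vehicle replicate C at 3 dpa, and of cyp1c1 and rspo1 on C at 5 dpa. The sizes of these rises therefore rest on the background correction. At 1 dpa the fold of cyp1a moved by over 1.5 times without vehicle replicate B, D or E, and those of cyp1c1, rspo1 and mmp13a without B. The count was 98 without vehicle replicate B, 11 without D, 15 without E and 24 without TCDD replicate A. With the letter as a block over all days, 17 were higher and 28 lower, and 69 passed with the block within the day. That last fit holds only the arrays of the day and leaves few residual degrees of freedom. With only the letters held by both exposures 3 passed, and with only the groups compared in the fit limma gave 0, with 883 at an unadjusted p under 0.05. The blocked adjusted p was 0.11 for mmp13a, 0.072 for sult6b1, 0.056 for sox9b and 0.055 for grna.1.

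The structural matrix list passed downward at 1 dpa at the preset correlation. Of 35 measured members, 1 fell (sparc, a collagen-binding matrix protein, by 0.72 ± 0.12), and 10 fell and 1 rose when adjusted over the list alone. The list median was -0.36 (camera adjusted p = 8.84e-10), with adjusted p = 0.168 with an estimated correlation. The call for sparc was lost without vehicle replicate D or E, or TCDD replicate A or B (adjusted p up to 0.132). Of 27 myeloid genes, the set named mpx rose while grna.1, of the granulin family, fell by 1.38 and the complement gene c1qc by 1.30. Adjusted over the list alone, 1 rose and 5 fell, and the list median was -0.28 (camera adjusted p = 3.35e-07), with adjusted p = 0.227 with an estimated correlation. The call for grna.1 was lost without vehicle replicate E (adjusted p = 0.0542), and that for c1qc without any 1 of 12 arrays (up to 0.246), after quantile normalization (0.0583) and after median centring (0.0553). None of the 53 cell cycle genes passed by limma over all genes or adjusted over the list alone. Over all genes 26 of 8793 passed, with 1242 probe sets at an unadjusted p under 0.05 on the whole array. The median of the cell cycle genes was -0.21 (camera adjusted p = 1.87e-06), with adjusted p = 0.559 with an estimated correlation. The median of this list was 0.07 at 3 dpa, 0.05 at 5 dpa and -0.06 on the mean of the 3 days, where it did not pass (camera adjusted p = 0.595, 0.674 and 0.221).

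**Figure D1:**
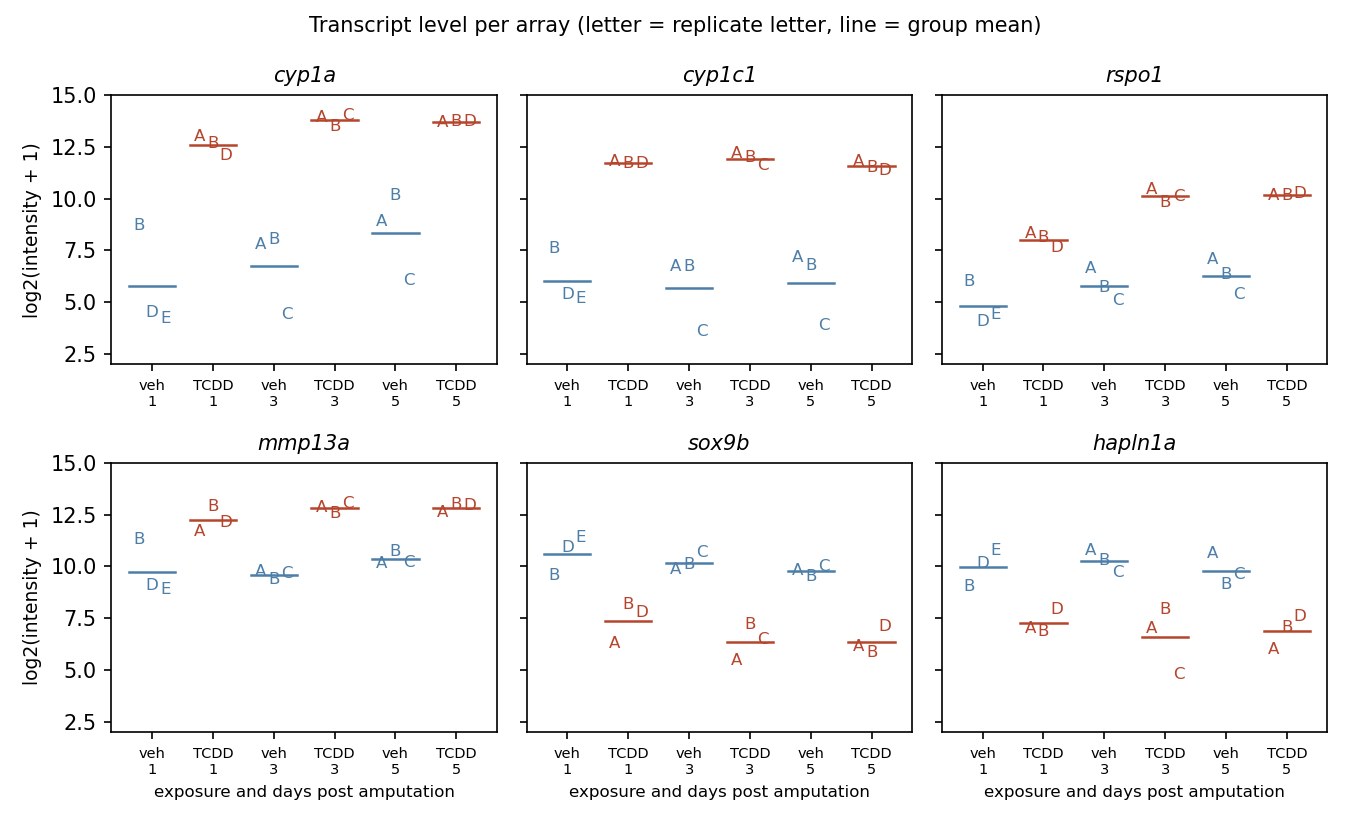
Level of 6 transcripts on each of the 18 arrays, as log2(intensity + 1), by exposure (veh, vehicle) and day post amputation. Each letter is 1 array of that replicate letter and each line a group mean of 3 arrays. At 3 dpa cyp1c1 averaged 5.67 in vehicle and 11.92 in TCDD fish, and sox9b 10.19 and 6.36.

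At 3 dpa, cyp1a rose 133-fold (adjusted p = 0.007), cyp1c1 75.7-fold (adjusted p = 0.0018) and rspo1 20.1-fold (adjusted p = 0.00035). mmp13a rose from 9.59 ± 0.19 to 12.81 ± 0.23 (n = 3), 9.30-fold. sox9b fell by 3.82 ± 0.55 (14.2-fold, adjusted p = 0.0023). and2, an actinodin of the fibres that stiffen the fin margin, fell by 2.83 ± 0.37 (adjusted p = 0.0011). hapln1a, which links hyaluronan to proteoglycans, fell by 3.67 ± 0.68, and ifitm5, an osteoblast membrane protein, by 3.15 ± 0.60. Other sets of hapln1a fell by 4.23 (adjusted p = 0.00035) and fell by 3.90 (adjusted p = 0.0032).

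In all, 172 probe sets passed at 3 dpa, 59 higher and 113 lower. nt5c2l1, cyb5a (cytochrome b5) and zdhhc2 also rose, by 3.05, 2.94 and 2.76, and the set named mpx by 3.91. These and cyp1a, cyp1c1, rspo1, mmp13a, sox9b and and2 passed with each array left out in turn. The genes hapln1a, ifitm5, fabp7a, ncana, loxa, hsd17b8, sst1.1 and sox19b lost the call without 2 to 4 of the 6 arrays of that day (adjusted p up to 0.132 for sox19b and 0.0794 for hapln1a), and sox19b also with a pseudocount of 16 (0.0526). A second probe set of hsd17b8 had a log2 difference of 0.05 against -2.49 for the set named, a second set of nfe2l2a 0.10 against 1.06, and dim second sets of sox9b and gch2 -0.18 and -0.22. The count was 72 and 82 without vehicle replicate A or C, and 75 and 82 without TCDD replicate A or C. It was 489 with the letter as a block, 59 with only the groups compared in the fit, and 36 without both arrays of letter C, whose GAPDH difference reached 4.06. The actin difference of these arrays was 1.626 in vehicle and 2.096 in TCDD fish, within the range of the other arrays. Leaving out vehicle replicate C or B gave 59.1- and 209-fold for cyp1a, and leaving out C gave 36.9-fold for cyp1c1.

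Some members of the matrix and retinoid lists fell at 3 dpa. Of 35 structural genes 3 fell (and2, hapln1a and vcanb) and none rose, and 9 fell adjusted over the list alone. Their median was -0.44 (camera adjusted p = 6.88e-08), with adjusted p = 0.217 with an estimated correlation. Of 25 matrix processing genes 5 fell, among them p4ha1b, a subunit of collagen prolyl hydroxylase, by 2.17 ± 0.28, and loxa, which crosslinks collagen, by 2.58 ± 0.48. mmp13a was the 1 that rose, and 8 fell adjusted over the list alone. Of these 6 calls, those of mmp13a and p4ha1b held with every array left out. The median was -0.10 (camera adjusted p = 0.000323), with adjusted p = 0.265 with an estimated correlation. Among 19 retinoid genes, cyp26b1, which degrades retinoic acid, fell by 1.32 ± 0.15 and stra6, a retinol transporter, by 1.37 ± 0.23, with 5 falling adjusted over the list alone. That list's median was 0.02 although its mean was -0.31 and its test pointed down (camera adjusted p = 0.00181), with adjusted p = 0.0629 with an estimated correlation. Of 16 antioxidant genes 3 rose, by the list alone also 3: gpx1b (1.32 ± 0.18), gstp1.2 and nfe2l2a (camera adjusted p = 0.00152, and adjusted p = 0.227 with an estimated correlation). The calls for gstp1.2 and nfe2l2a were lost without vehicle replicate A or C or TCDD replicate C, and that for nfe2l2a also without TCDD replicate A (adjusted p up to 0.108), and that for vcanb without any 1 of 13 arrays (up to 0.176). tiparp, an AHR target, had a log2 difference of 1.07 (adjusted p = 0.069, and 0.024 with the letter as a block). nqo1, another AHR target, had 0.78 (adjusted p = 0.39).

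At 5 dpa, cyp1c1 rose 49.8-fold (adjusted p = 0.0042), cyp1a 40.6-fold (adjusted p = 0.032) and rspo1 15.1-fold (adjusted p = 0.0011). sox9b fell by 3.42 ± 0.55 and loxa from 10.47 ± 0.34 to 7.22 ± 0.72 (n = 3), 9.56-fold (adjusted p = 0.0034). gch2, an enzyme of pteridine pigment synthesis, fell by 2.40 ± 0.31 (adjusted p = 0.0013), and the keratin gene krt94 by 2.19 ± 0.37. hgd, an enzyme of tyrosine breakdown, fell by 2.95 ± 0.46, fabp7a, a fatty acid binding protein, by 2.86 ± 0.49, and f13a1b, a clotting factor subunit, fell by 1.96 ± 0.32. jac4 rose by 4.10 ± 0.74 and ntrnl2 by 4.49 ± 0.80, with adjusted p up to 0.0441 and 0.0484 when 1 array was left out.

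In all, 255 probe sets passed at 5 dpa, 119 higher and 136 lower. Median centring of the arrays gave 101 higher and 174 lower, but the majority turned to the higher ones after quantile normalization (119 and 110), without dim probe sets (144 and 117) and with a constant prior (142 and 130). The count was 520 with the letter as a block over all days but 1 with the block within the day. That last fit holds only the arrays of the day, and letters C and D, each in 1 exposure, carry no TCDD effect in it. Few residual degrees of freedom remain there, so that its count says little about stability. The count was 31 with only the letters held by both exposures and 115 with only the groups compared in the fit. It was 150 and 135 without vehicle replicate A or C, and 126, 142 and 146 without TCDD replicate A, B or D. The rise of cyp1a was 18.3-fold without vehicle replicate C and 75.2-fold without B, and that of cyp1c1 24.4-fold without C and 76-fold without A. The call for cyp1a was lost without any 1 of 5 arrays (adjusted p up to 0.116), and those for mmp13a (5.63-fold) and gstp1.2 without vehicle replicate A or C or TCDD replicate B (adjusted p up to 0.0536 and 0.0683). The vehicle level of cyp1a differed between letters over the 3 days: 7.78 to 10.13 on 5 arrays of letters A and B, and 4.19 to 6.06 on 4 arrays of C, D and E. For cyp1c1 these ranges were 6.70 to 7.57 and 3.60 to 5.38. Other sets of cyp1c1 differed less: at 1, 3 and 5 dpa 1 had 2.86, 3.78 and 3.19 (adjusted p = 0.3, 0.045 and 0.074) and a dimmer set 0.31, 0.29 and -0.01 (adjusted p = 0.58, 0.46 and 0.99).

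The retinoid list fell at 5 dpa with either correlation (camera adjusted p = 3.05e-05, and adjusted p = 0.0214 with an estimated correlation). Of its 19 members 4 fell and none rose, and 7 fell adjusted over the list alone: stra6 fell by 1.69 ± 0.23, cyp26b1 by 1.24 ± 0.15, dhrs3a, a retinal reductase, by 1.21 ± 0.23 and the receptor gene rxrga by 1.06 ± 0.21. The calls for dhrs3a and rxrga were lost without vehicle replicate C, that for dhrs3a also without TCDD replicate B and that for rxrga without TCDD replicate A or D (adjusted p up to 0.0633 and 0.0942). Of 16 antioxidant genes 3 rose and 8 rose adjusted over the list alone, with gpx1b, a glutathione peroxidase, up by 1.88 ± 0.18 and gsr, glutathione reductase, by 0.90 ± 0.16 (camera adjusted p = 2.26e-05, and adjusted p = 0.162 with an estimated correlation). Of 35 structural matrix genes 5 fell, 8 adjusted over the list alone against 1 that rose (median -0.35, camera adjusted p = 9.21e-06, and adjusted p = 0.265 with an estimated correlation). None of these 5 calls held with every array left out: hapln1a was lost without any 1 of 13 arrays (adjusted p up to 0.15), col11a2 of 14 (0.135), vcanb of 5 (0.109) and bgnb of 5 (0.0949, and 0.06 with the letter as a block). Of 17 pigment cell genes gch2 and slc2a15b fell, and 3 adjusted over the list alone (median -0.30, camera adjusted p = 0.000778, and adjusted p = 0.249 with an estimated correlation). Of 51 blastema and patterning genes 3 rose (rspo1, il17rd by 1.52 ± 0.26 and msx2b by 1.94 ± 0.45) and and2 fell, with 10 and 5 adjusted over the list alone. That list as a whole did not pass (camera adjusted p = 0.276). The call for msx2b was lost without any 1 of 10 arrays (adjusted p up to 0.153), and slc2a15b's without vehicle replicate A or C or TCDD replicate B or D (up to 0.062). The call for and2 was lost without vehicle replicate C (adjusted p = 0.0536).

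**Figure D2:**
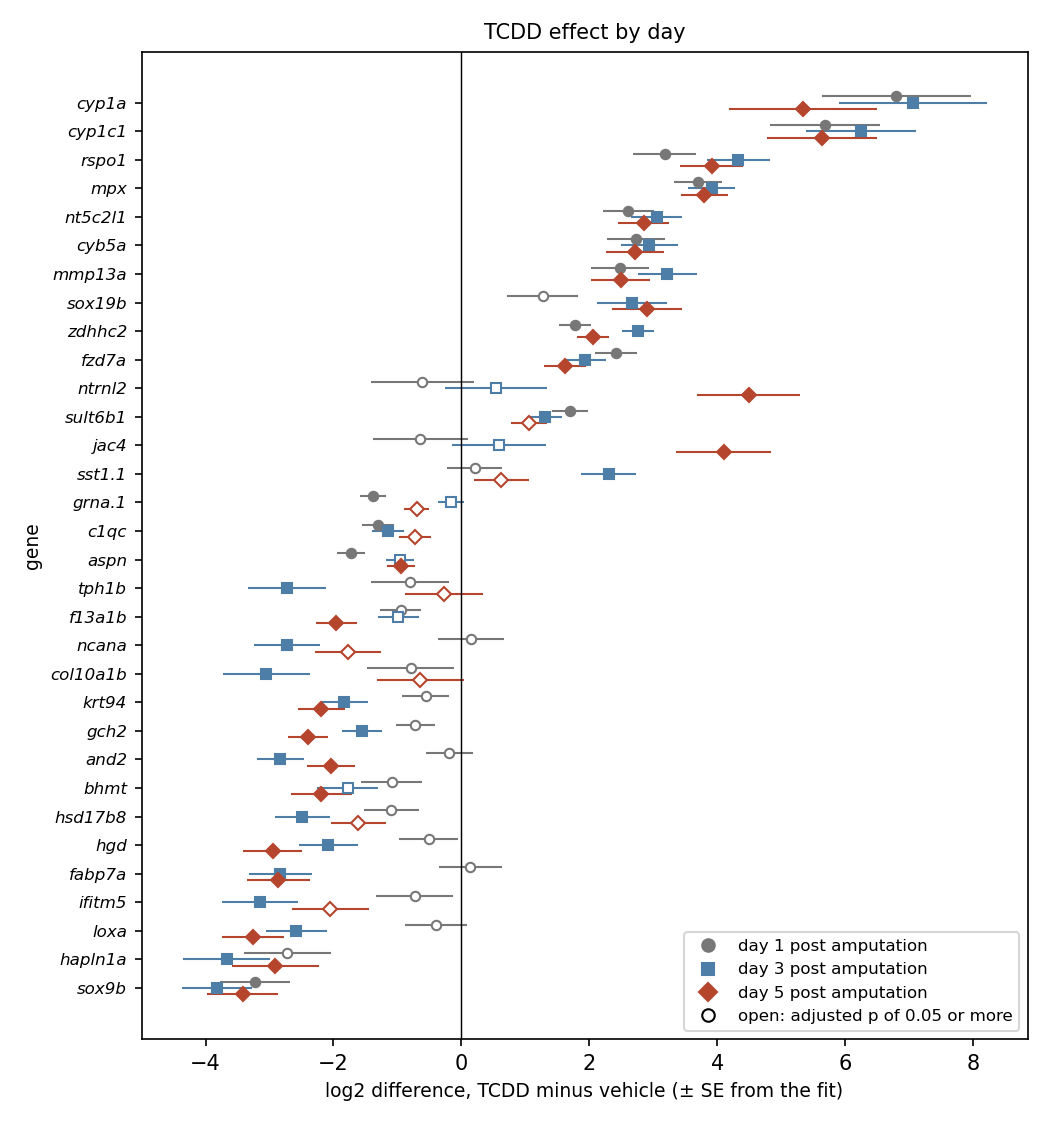
Log2 difference between TCDD and vehicle fish, with its SE from the fit, for the genes with the largest rises and falls at each day. Shape and colour give the day, and open symbols an adjusted p of 0.05 or more. At 1 dpa cyp1a differed by 6.80 and sox9b by -3.23.

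On the mean of the 3 days, which sets 9 arrays against 9, matrix genes fell in the largest numbers among the lists. Of 35 structural genes 12 fell and none rose, and 20 fell and 1 rose adjusted over the list alone. hapln1a fell by 3.10 ± 0.39, vcanb (versican) by 1.78 ± 0.24, and2 by 1.69 ± 0.21 and the collagen gene col11a1a by 1.30 ± 0.20. The call for col18a1a, 1 of the 12, was lost with the letter as a block (adjusted p = 0.051) and without any 1 of 8 arrays (up to 0.066). The list passed at the preset correlation (camera adjusted p = 2.36e-13) but had adjusted p = 0.0523 with an estimated correlation. Of 25 processing genes 9 fell, led by loxa (-2.08 ± 0.28), p4ha1b (-1.45 ± 0.16) and loxl2b (-1.10 ± 0.16), while mmp13a (2.73 ± 0.27) and timp2b rose. The call for timp2a, 1 of the 9, was lost with the letter as a block (adjusted p = 0.068) and without any 1 of 13 arrays (up to 0.085). Adjusted over the list alone 11 fell and 2 rose (camera adjusted p = 2.68e-06, and adjusted p = 0.12 with an estimated correlation). The AHR target list (4 of 5 rose, and 5 adjusted over the list alone) and the retinoid list (4 of 19 fell, and 6 adjusted over the list alone against 1 that rose) passed with either correlation, with adjusted p = 0.0264 and adjusted p = 0.00426 with an estimated correlation. tiparp rose by 0.80 ± 0.15 and the receptor gene ahr2 by 0.36 ± 0.08.

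In all, 586 probe sets passed on the mean effect, 264 higher and 322 lower, and 1063 with the letter as a block. The count was 385 without letter C at 3 dpa and 259 with only the letters held by both exposures. Of 27 myeloid genes marco, a macrophage receptor, fell by 1.52 ± 0.23 and c1qc by 1.05 ± 0.14, and 5 fell and 2 rose in all, 9 and 3 adjusted over the list alone. That list had a camera adjusted p of 0.000304, and adjusted p = 0.496 with an estimated correlation. Of 30 bone and cartilage genes sox9b (-3.49 ± 0.32), runx2a (-1.05 ± 0.14) and col10a1a (-1.32 ± 0.28) fell and bmp2a rose by 0.92 ± 0.19, with 4 and 1 adjusted over the list alone. The list did not pass (camera adjusted p = 0.158). A dimmer second set of runx2a had a log2 difference of 0.20 at 3 dpa against -1.07, a call lost without any 1 of 15 arrays (adjusted p up to 0.171). Calls for timp2b and spi1b were lost without any 1 of 13 and of 9 arrays (adjusted p up to 0.099 and 0.067).

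**Figure D3:**
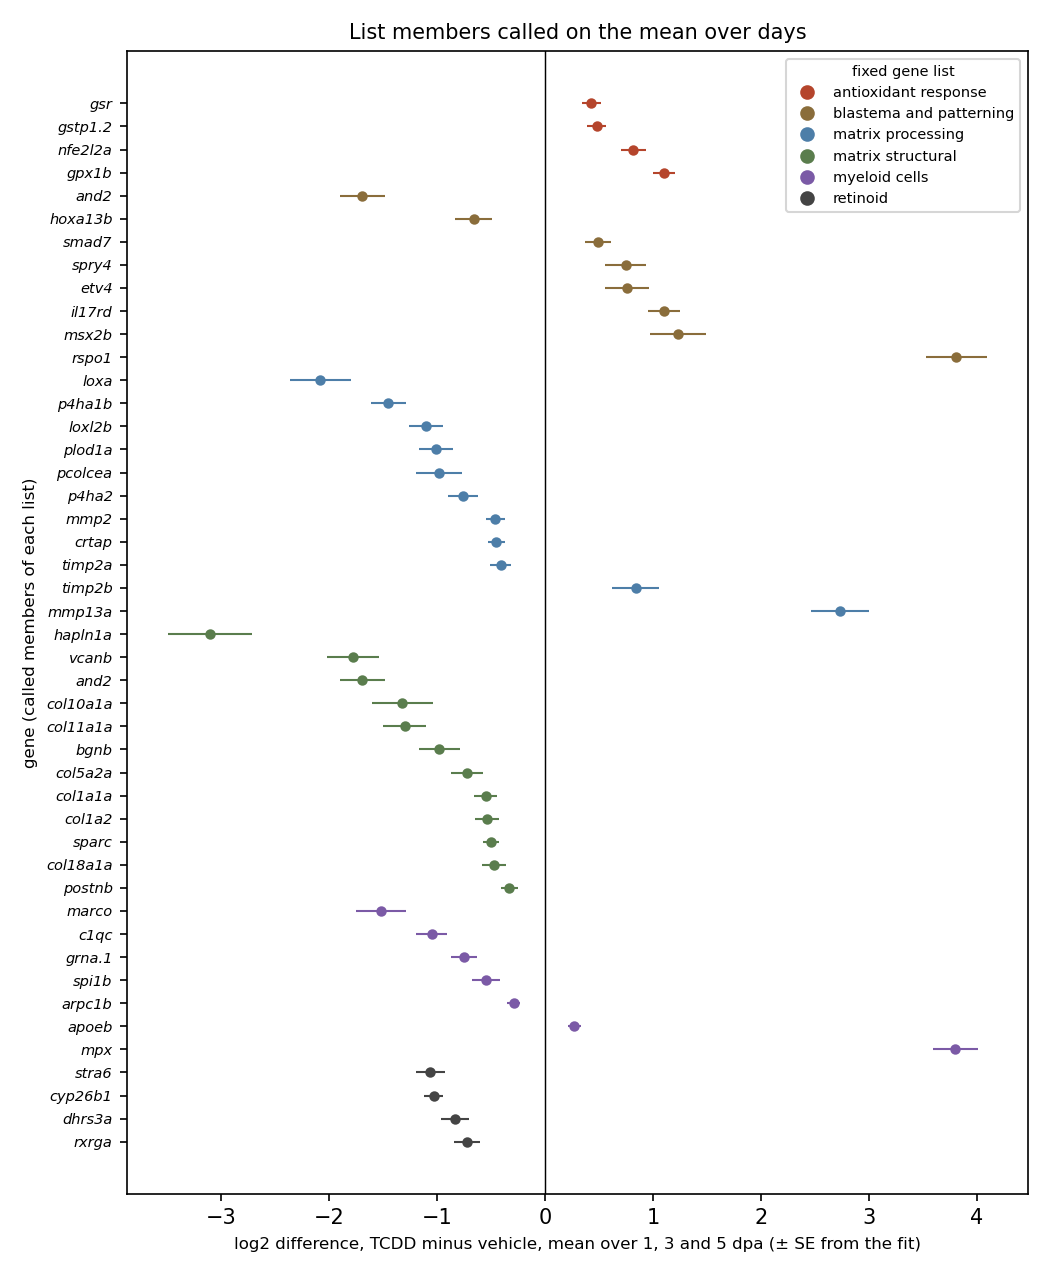
Log2 difference between TCDD and vehicle fish on the mean of 1, 3 and 5 dpa, with its SE from the fit, for the members of 6 fixed gene lists that passed at an adjusted p under 0.05. Colours give the list. hapln1a lies lowest at -3.10 and rspo1 highest at 3.81.

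Of 51 blastema and patterning genes 6 rose and 2 fell on the mean effect, 12 and 8 adjusted over the list alone. rspo1 rose by 3.81 ± 0.28, msx2b by 1.23 ± 0.26 and il17rd by 1.1 ± 0.15, and these and and2 held with every array left out, while spry4, etv4, smad7 and hoxa13b did not (adjusted p up to 0.099). The list did not pass (camera adjusted p = 0.345). Of 16 antioxidant genes 4 rose, 6 adjusted over the list alone, with gpx1b up by 1.1 ± 0.1 and nfe2l2a, a regulator of antioxidant genes, by 0.82 ± 0.12 (camera adjusted p = 0.000217, and adjusted p = 0.12 with an estimated correlation). Of 17 pigment cell genes gch2 fell by 1.56 ± 0.18, and slc2a15b and slc2a11b also fell, 3 as well adjusted over the list alone (camera adjusted p = 0.0276, and adjusted p = 0.496 with an estimated correlation).

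On the mean effect, of 56 oxidative phosphorylation genes none passed by limma over all genes or adjusted over the list alone (median 0.13, camera adjusted p = 2.68e-06, and adjusted p = 0.621 with an estimated correlation). Over all genes 382 of 8793 passed, with 2413 probe sets at an unadjusted p under 0.05 on the whole array. Of 18 erythrocyte genes only nt5c2l1 rose, also adjusted over the list alone (camera adjusted p = 0.0281, and adjusted p = 0.496 with an estimated correlation). The camera adjusted p was 0.91 for the AHR complex (ahr2 rose, 1 of 8), 0.41 for the epidermis (3 rose and 1 fell of 42), 0.808 for inflammation (none of 35), 0.808 for lymphocytes (none of 7), 0.808 for skeletal muscle (mb passed downward, 1 of 36, with adjusted p = 0.056 with the letter as a block and up to 0.079 without any 1 of 13 arrays) and 0.885 for the vascular endothelium (plvapb fell, 1 of 19). It was 0.762 for nerve and glia (1 rose of 20), 0.848 for sterol synthesis (none of 13), 0.055 for unfolded protein and heat shock (none of 34, and 0.0174 with the letter as a block, where it had adjusted p = 0.631 with an estimated correlation), 0.91 for glycolysis (2 rose and 1 fell of 29), 0.295 for liver and plasma (1 rose and 1 fell of 28) and 0.432 for ribosomal proteins (none of 70). Of the members called here, mbpb of nerve and glia lost the call without any 1 of 12 arrays (adjusted p up to 0.07), gpia of glycolysis of 10 (0.072), krt17 of the epidermis of 9 (0.07) and apoc1 of liver and plasma of 8 (0.058). elf3 of the epidermis lost it without 1 array (0.053). Adjusted over the list alone, 1 AHR complex gene rose, 3 epidermis genes rose and 4 fell, 2 vascular genes rose and 2 fell, 2 liver and plasma genes rose and 1 fell, and no inflammation, lymphocyte, sterol, heat shock or ribosomal gene passed. Among these lists the median, the mean and the direction of the test differed in sign for the AHR complex, inflammation, lymphocytes, skeletal muscle, vascular endothelium, nerve and glia, and glycolysis.

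Within days, further lists passed at the preset correlation but not with an estimated one. At 1 dpa the AHR target list passed upward (cyp1a and cyp1c1 of 5, and 3 adjusted over the list alone; camera adjusted p = 0.000395, and adjusted p = 0.217 with an estimated correlation). At 3 and 5 dpa 3 of the 5 rose, and 5 and 3 adjusted over the list alone (camera adjusted p = 6.16e-08 and 3.38e-05), with adjusted p = 0.0629 and adjusted p = 0.168 with an estimated correlation. The matrix processing list passed downward at 1 and 5 dpa (camera adjusted p = 1.31e-05 and 0.0264), with adjusted p = 0.218 and adjusted p = 0.603 with an estimated correlation. The call at 5 dpa was lost without vehicle replicate C or TCDD replicate A or B (adjusted p up to 0.195). The bone and cartilage list passed downward at 5 dpa (sox9b, runx2a and twist1a fell of 30; camera adjusted p = 0.0184, and adjusted p = 0.417 with an estimated correlation), a call lost without TCDD replicate A or B (adjusted p up to 0.103). The call for twist1a was lost without any 1 of 13 arrays (adjusted p up to 0.162) and that for runx2a without vehicle replicate A or TCDD replicate A or B (up to 0.0572). The skeletal muscle list had a median of -0.12 at 5 dpa, although tnni2b.1 rose by 1.41 ± 0.28, a call lost without vehicle replicate A or B or TCDD replicate A or D (adjusted p up to 0.0876) (camera adjusted p = 0.00145, and adjusted p = 0.478 with an estimated correlation). This call was lost without dim probe sets (median 0.017, adjusted p = 0.89) and after quantile normalization (-0.008, adjusted p = 0.318). The nerve and glia and the liver and plasma lists passed downward at 5 dpa (camera adjusted p = 0.0208 and 0.0204, with adjusted p = 0.478 and adjusted p = 0.559 with an estimated correlation). None of their 20 and 28 genes passed by limma. Over all genes 168 of 8793 passed, with 2736 probe sets at an unadjusted p under 0.05. Both of these list calls at 5 dpa were lost with the letter as a block (0.121 and 0.0721). At 1 dpa the liver and plasma list had passed upward (median 0.193, camera adjusted p = 0.000323, and adjusted p = 0.265 with an estimated correlation). That call was lost after quantile normalization (camera adjusted p = 0.112). Oxidative phosphorylation passed at 1, 3 and 5 dpa (camera adjusted p = 0.000323, 0.00641 and 0.00181) and erythrocytes at 1 and 3 dpa (0.00138 and 0.0147), with positive medians. Retinoid and epidermis passed at 1 dpa (0.0455 and 0.0203) and heat shock at 3 dpa (0.022), with negative medians. With an estimated correlation all had adjusted p of 0.217 or more. Only oxidative phosphorylation at 5 dpa held with every array left out. The block made 4 calls within days, none of which passed when the blocked test was repeated with an estimated correlation, a choice made after seeing the data. The inflammation list passed downward at 1 dpa (3.98e-05, against 0.711 without the block), with adjusted p = 0.44 with an estimated correlation. It passed upward at 3 dpa (0.0348, against 0.206), with adjusted p = 0.726 with an estimated correlation. The vascular list passed upward at 1 dpa (0.0337, against 0.101), with adjusted p = 0.651 with an estimated correlation. The ribosomal list passed downward at 5 dpa (0.0489, against 0.124), with adjusted p = 0.862 with an estimated correlation.

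The TCDD effects of different days overlapped. Their group means share no arrays, but the estimate of the spread per probe set is shared, which can add to the overlap. Between 1 and 3 dpa 16 probe sets were higher on both days, against 0.0952 for independent lists, and 7 lower against 0.0948. Between 3 and 5 dpa 33 were higher against 0.453 and 35 lower against 0.991. No probe set passed in opposite directions on any pair of days. On all 3 days 12 probe sets were higher, among them those of cyp1a, cyp1c1, rspo1, mmp13a, fzd7a and zdhhc2, and 4 were lower, among them sets of sox9b and hapln1a.

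The F test for a TCDD effect that differs between days passed for 8 probe sets, 4 of them with a symbol. gpx1b rose by 1.32 ± 0.18 at 3 dpa and 1.88 ± 0.18 at 5 dpa, with 0.09 ± 0.18 at 1 dpa (adjusted p of the F test = 0.038). calb2a, a calcium-binding protein, differed by -0.21, -2.15 and -0.28 at 1, 3 and 5 dpa (adjusted p = 0.041), and anxa6, an annexin, by 0.07, -0.23 and -1.18 (adjusted p = 0.03). With the letter as a block 1 passed, and gpx1b, calb2a and anxa6 had adjusted p of 0.14, 0.12 and 0.14. The count was 13 without vehicle replicate B at 3 dpa. It was 1 without vehicle replicate B or D at 1 dpa, vehicle A or B at 5 dpa or TCDD B or D at 5 dpa, and 2 without TCDD A at 3 dpa. It was 3 without vehicle E or TCDD B at 1 dpa or vehicle C at 5 dpa, 4 without vehicle A at 3 dpa or TCDD A at 5 dpa, and 5 without TCDD A or D at 1 dpa.

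From 1 to 3 dpa in vehicle fish, the 5 largest rises by the naming rule were those of and2, enam, and1, ifitm5 and col10a1a. and2 rose by 8.04 ± 0.37 (from 3.92 ± 0.40 to 11.95 ± 0.46, n = 3), but its level at 1 dpa lies under the 40th percentile of each array, so that the size of this rise rests on the background correction. and1 rose 66.8-fold, enam, an enamel matrix protein, 121-fold, ifitm5 66.8-fold and col10a1a, a collagen of skeletal cells, 47.6-fold. Without vehicle replicate B or D at 1 dpa the rise was 66.4- or 240-fold for enam and 42.8- or 110-fold for and1. gda, guanine deaminase, fell by 3.44 ± 0.35, gap43, a growth cone protein, by 2.64 ± 0.34 and fosl1b, a transcription factor of the AP-1 family, by 2.52 ± 0.41. Of 35 structural matrix genes 14 rose and 2, fn1a and fn1b, fell (17 and 2 adjusted over the list alone), and 13 of the 16 calls held with every array left out. The letter as a block ended the calls of fn1b (adjusted p = 0.0883) and bgnb, and that of fn1a was lost without any 1 of 3 arrays (adjusted p up to 0.0793). Of 51 blastema and patterning genes 9 rose and 1 fell (18 and 3 adjusted over the list alone), with msx3 up by 1.92 ± 0.21 and msx1b by 1.49 ± 0.23. Of 30 bone and cartilage genes 8 rose (11, against 1 that fell, adjusted over the list alone), with runx2a up by 2.22 ± 0.24. The camera adjusted p was 6.66e-12, 2.8e-07 and 7.94e-06 for these lists, with adjusted p = 0.184, adjusted p = 0.219 and adjusted p = 0.184 with an estimated correlation. Of 29 glycolysis genes 5 fell, 8 adjusted over the list alone (camera adjusted p = 0.00418, and adjusted p = 0.41 with an estimated correlation).

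In all, 854 probe sets passed over this step, 540 higher and 314 lower. With the letter as a block 941 passed, of which 553 are among the 854. The 10 genes with the largest changes kept the call with each array left out, though bhlha9 had an adjusted p of 0.057 with the letter as a block. The count was 175 with only the groups compared in the fit, 335 without letter C at 3 dpa and 465 with only the letters held by both exposures. It was 339 and 544 without vehicle replicate C or A at 3 dpa, and 522 and 482 without D or E at 1 dpa. With the block, the inflammation list passed downward (camera adjusted p = 0.000924, against 0.985 without the block), but had adjusted p = 0.535 with an estimated correlation. The myeloid list also passed downward (0.00327, against 0.407), with adjusted p = 0.563 with an estimated correlation. The cell cycle list passed downward without the block (orc1 and pold1 fell of 53, also adjusted over the list alone; median -0.15, camera adjusted p = 0.0346, and adjusted p = 0.807 with an estimated correlation), a call lost with it (0.991).

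From 3 to 5 dpa in vehicle fish 53 probe sets passed, 22 higher and 31 lower. With the letter as a block 322 passed, with only the groups compared 2, with only the letters held by both exposures 9 and without letter C at 3 dpa 22. and3, an actinodin, rose by 3.03 ± 0.41 (adjusted p = 0.0083) and hspb8, a small heat shock protein, fell by 1.81 ± 0.21 (adjusted p = 0.0029), both with each array left out in turn. has2, a hyaluronan synthase, fell by 2.12 ± 0.31, a call lost without replicate B at 3 or 5 dpa (adjusted p up to 0.0612). Of 35 structural matrix genes thbs4b, a thrombospondin, rose by 1.42 ± 0.25, and 5 rose adjusted over the list alone (camera adjusted p = 2.54e-05, and adjusted p = 0.41 with an estimated correlation). The call for thbs4b was lost without any 1 of 6 arrays (adjusted p up to 0.116). The 53 cell cycle genes had a median of -0.24, with none passing in limma over all genes or the list alone (camera adjusted p = 0.00061, and adjusted p = 0.74 with an estimated correlation). Over all genes 33 of 8793 passed, with 1872 probe sets at an unadjusted p under 0.05. With the block the myeloid list passed upward (0.0157, against 0.0759 without the block) and the heat shock list downward (0.0289, against 0.0759), with adjusted p = 0.633 and adjusted p = 0.661 with an estimated correlation. Median centring turned the split to 26 higher and 18 lower. The count was 7 without vehicle replicate B at 5 dpa, 10 without A or B at 3 dpa, 13 without A at 5 dpa and 17 without C at 3 dpa. It was also 17 and 25 without TCDD replicate A or B at 3 dpa, and 23 and 29 without vehicle replicate E or TCDD replicate B at 1 dpa.

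In TCDD fish 1670 probe sets passed from 1 to 3 dpa, 734 higher and 936 lower. Without letter C at 3 dpa in both exposures 923 passed, without TCDD replicate C there 936, with only the groups compared 754 and with only the letters held by both exposures 1105. enam rose by 8.20 ± 0.69, and1 by 7.26 ± 0.50 and and2 by 5.39 ± 0.37. Of 35 structural matrix genes 15 rose and 2 fell, 16 and 2 adjusted over the list alone (camera adjusted p = 1.81e-08, and adjusted p = 0.214 with an estimated correlation). Across all probe sets the step in TCDD fish correlated with that in vehicle fish (r = 0.757, rho = 0.651; probe sets are not independent replicates). 320 probe sets rose in both, against 25.6 for independent lists, and 234 fell in both, against 19. The group means of these steps share no arrays, but the estimate of the spread per probe set is shared. Both steps bring in letter C and drop letter D, so that effects of these letters can also add to the overlap. Without letter C at 3 dpa and letter D at 1 dpa, a choice made after seeing the data, r was 0.721, with 90 rising in both, against 2.77, and 28 falling in both, against 1.15. No probe set passed limma's test that the step differed between exposures, with 669 at an unadjusted p under 0.05. From 3 to 5 dpa in TCDD fish 2 passed: and3, up by 3.00 ± 0.41 (adjusted p = 0.02, and 0.14 with the letter as a block), and a probe set without a symbol. The count was 0 without TCDD replicate A at 3 dpa or D at 5 dpa, 9 without B at 3 dpa and 5 without A at 5 dpa, with 1028 at an unadjusted p under 0.05 in limma's test of all arrays.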

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

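The tests of the mpx probe set were chosen only after the result was seen, as was the comparison of each bound with its spread over other splits, without which the bounds would argue against unequal letters and an earlier stage. The TCDD effect differed between days by limma's F test for 8 probe sets. The adjusted p was 0.041 for cyp2k6, a dim transcript (log2 differences 0.36, 0.05 and -0.11 at 1, 3 and 5 dpa), 0.041 for calb2a, 0.03 for anxa6, also dim, and 0.038 for gpx1b. For 4 probe sets without a symbol it was 0.0039 (0.05, -0.28 and -3.87), 0.022 (-2.41, -1.28 and -0.52), 0.03 (-0.10, -0.26 and -1.53) and 0.022 (0.22, 0.13 and -0.40). With the letter as a block only the first of these 4 passed (adjusted p = 0.0058). Of 100 splits of the arrays within days, 4 gave 8 or more such probe sets, the highest of the others 26.

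For the mean TCDD effect, 1 of 100 splits within days, the real one, gave 586 probe sets or more, and the highest other gave 39. These splits do not keep the pairing by letter. Only 11 of the others drawn part 7 same-letter pairs as the real grouping does, and the highest of these gave 3. These 11 are too few for a share under 0.05. The arrays allow more splits of that kind, but they were not drawn. Chance is therefore not excluded once the pairing is kept. The comparisons of 3 arrays with 3 have only 10 splits, too few for a share under 0.05. Their real and highest other counts were 172 and 2 at 3 dpa, 255 and 1 at 5 dpa, 854 and 0 for the vehicle step from 1 to 3 dpa, and 53 and 2 for that from 3 to 5 dpa. In TCDD fish they were 1670 and 2, and 2 and 1. At 1 dpa 2 of 10 splits gave 38 or more: a split of letters A and B against D and E, which parts no same-letter pair, gave 98, which points to a structure of these arrays by letter. The real grouping parts 2 pairs, and the highest of the 3 other splits parting 2 pairs gave 0 in the same fit. With the letter as a block within the day, a fit with few residual degrees of freedom, the real grouping gave 69. The other splits were not run with the block.

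The probe set named mpx with the highest mean rose at all 3 days, by 3.80 ± 0.21 on their mean. Its mean over all arrays, 5.62, is the highest of the mpx sets only because it includes that rise. More neutrophils in the TCDD tissue would raise the other sets of this symbol, but the 1 other set with a mean level of 5 or more had a log2 difference of -0.043 ± 0.37, and lyz, another neutrophil gene, 0.16 ± 0.51 (adjusted p = 0.93). A candidate explanation is that the set measures a transcript that follows cyp1a: its deviations from the group means correlated with those of cyp1a at 0.776, above 99.8% of probe sets. However, 2 other mpx sets with mean TCDD effects of -0.243 and -0.043 correlated with cyp1a at 0.679 and 0.369, so that a high correlation does not single out an induced transcript. The mpx sets share a cluster number in their names with the cyp1a set, their sequences were not analysed here, and an induced mpx transcript that only 1 set detects stays open.

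Of 351 genes that rose from 1 to 3 dpa in vehicle fish, 72.1% were lower with TCDD at 5 dpa, with a median of -0.29, and of 238 that fell 69.3% were higher. Other splits of the same arrays gave medians as far from 0 as 0.29, so that the pattern is no larger than a regrouping of the arrays can give. With the GAPDH difference as a covariate the median was -0.289, beyond the bound of -0.1 by more than the spread of 0.161 over other splits. Another split gave -0.307 in the same fit, though. The group means of the GAPDH difference at 5 dpa were also close (1.86 in vehicle and 2.12 in TCDD fish), so that the covariate could move the median little. RNA quality as a source therefore stays open, and the actin difference was not tried as a covariate. Unequal letters cannot be told apart: at 3 dpa, where both exposures hold the same letters, 656 genes that rose from 1 to 5 dpa had a median of -0.112, past the bound by less than the spread of 0.089. An earlier stage of the regenerate in TCDD fish may contribute but also stays open, since 58.8% of the rising genes were lower at 3 dpa while 34.7% of 1255 falling genes were higher, with spreads of 12.7 and 15.8 points.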

How the results depend on the processing

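The random block, the GAPDH covariate and the 3 fits on fewer letters were chosen after seeing the data. Counts are given in the order 1 dpa, 3 dpa, 5 dpa, mean effect, day difference, vehicle 1 to 3 and 3 to 5 dpa, TCDD 1 to 3 and 3 to 5 dpa (38, 172, 255, 586, 8, 854, 53, 1670 and 2), and only where they moved by over 1.5 times; the cause was not tested unless given. Median centring moved none that far. With the letter as a replicate block over all days they were 489 (3 dpa), 520 (5 dpa), 1063 (mean), 1 (day difference), 322 (vehicle 3 to 5 dpa) and 1 (TCDD 3 to 5 dpa), with the block within the day 69, 283 and 1 (5 dpa), and with it as a random block (correlation 0.454) 130, 923, 1130, 1513 and 231. The blocked fits within the day hold only the arrays of that day and leave few residual degrees of freedom. Of 170 gene results the block over all days ended 21 calls and made 1, and of 120 list results it ended 3 and made 8. It changed no other call among these. On the mean effect it also ended calls of list members (col18a1a, timp2a and mb), made others and made that of the heat shock list. Of the called probe sets, those called with the block too were 24, 172, 224, 565, 1, 553, 53, 1526 and 1.

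With only the groups compared in the fit, which leaves fewer arrays, they were 0 (1 dpa), 59, 115, 175 and 2 (vehicle), 754 and 0 (TCDD). A minimum 2-fold change, a stricter limit by construction, gave 25, 112, 146, 142 (mean), 382 and 30 (vehicle) and 596. Array weights gave 264, 456 and 137 (vehicle 3 to 5 dpa). That last step gave 109 with a constant prior, 146 with the GAPDH covariate and 85 with a pseudocount of 16, which gave 0 for TCDD 3 to 5 dpa. The day difference gave 2 after quantile normalization, 1 without dim probe sets (9962 kept) and 3 with 1 probe set per gene, which gave 1 for TCDD 3 to 5 dpa.

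Without letter C at 3 dpa they were 36 (3 dpa), 385 (mean), 335 and 22 (vehicle), 923 and 0 (TCDD). With only letters held by both exposures they were 3 (1 dpa), 31 (5 dpa), 259 (mean), 0 (day difference), 465 and 9 (vehicle), 1105 and 0 (TCDD). Without letters A and B, 7 arrays and 1 residual degree of freedom remain, and 2 passed for the mean effect and 0 elsewhere, which says little about stability. There the oxidative phosphorylation list reversed from 3 to 5 dpa in vehicle fish (0.027, adjusted p = 0.25).

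Leaving out 1 array gave 11 to 98 at 1 dpa, 72 to 194 at 3 dpa, 126 to 288 at 5 dpa, 436 to 670 on the mean, 1 to 13 for the day difference, 339 to 900 and 7 to 63 (vehicle), and 936 to 1795 and 0 to 9 (TCDD). Of 155 gene calls followed, 70 held with every array left out, and none changed sign. An estimated correlation ended 45 of the 46 list calls within days and in the vehicle course, all but that of the retinoid list at 5 dpa. Of the 170 gene results, quantile normalization ended 9 calls, median centring 6 and a pseudocount of 16 ended 2.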

Other observations

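Of the myeloid list, marco had log2 differences of -2.00, -1.41 and -1.16 at 1, 3 and 5 dpa and a mean of -1.52 ± 0.23 (limma adjusted p = 0.00104). spi1b, a transcription factor of myeloid cells, fell by 0.55 ± 0.13 on the mean (adjusted p = 0.029), a call lost without any 1 of 9 arrays (up to 0.067). lcp1 and coro1a, expressed in leukocytes generally, had -0.475 ± 0.168 and -0.398 ± 0.135 (adjusted p = 0.159 and 0.138). csf1ra and cxcr4b, also of this list, had -0.285 ± 0.116 and -0.25 ± 0.21 (adjusted p = 0.238 and 0.639). lyz had 0.16 ± 0.51. None of lcp1, coro1a, csf1ra, cxcr4b and lyz passed.

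Vehicle arrays of letters A and B had rspo1 levels of 5.71 to 7.05 (5 arrays), and those of letters C, D and E 4.09 to 5.38 (4 arrays), in the same order as cyp1a and cyp1c1. These letters were noticed through the levels themselves, so no test was made.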
